A study of Arabidopsis thaliana with 4 samples.

How the data were processed

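RNA sequencing (total RNA, an Illumina HiSeq instrument) was available for 4 libraries, 1 for each combination of genotype (wild type Col-0 or lbd16-2) and day (0 or 4). Per the labels' protocols, plants were grown at 22 °C with 16 h light and 8 h dark, and the first pair of leaves of 12-day-old plants was placed on callus inducing medium in the dark. Per the submitters' processing notes, FastQC, Trim Galore, STAR, Cufflinks and DESeq were used with the TAIR10 genome. Their versions and settings, the use of strand and the handling of reads that match several genes are not given in the sources used here. Values of near-identical or overlapping genes, such as CDC20.1 and CDC20.2, GSTF6 and GSTF7, or CYP71A12 and CYP71A13, are therefore uncertain.

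The authors deposited 4 tables: the genes increased in wild type, the genes increased in lbd16-2, the genes in the wild-type list alone and the genes in both lists. The levels deposited per library are on a log2 scale. Their values are those of log2(reads divided by a size factor, plus 1), which was inferred from the values and is not stated by a header: when undone with 1 size factor per library, 100% of the values in each library came out as whole reads within 0.001 reads. The log2 fold changes the authors deposited equal the difference of these levels, so they are on the log2(normalised reads + 1) scale and understate the change of genes with few reads. The deposited ratio of the folds in the table of shared genes is the linear ratio of these folds between genotypes. The p-value and FDR columns are the authors' own, and how a p-value was obtained from 1 library per group is not given in the sources used here. Each list held the genes with a log2 fold above 3, an 8-fold increase, with no limit on the p-value. The number of genes the authors tested, 24442 in wild type and 24518 in lbd16-2, was recovered as the number that makes FDR-to-p ratios whole ranks most often, in 53.1% and 55.1% of genes, against 26.5% and 25.8% for the next best number.

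From the recovered reads, normalised reads per library (reads divided by the size factor) and linear folds without a pseudocount were computed. For a gene with 0 reads at day 0 the fold is given as a lower bound against a floor of 3 reads in that library, which is 2.09 normalised reads in wild type and 2.78 in lbd16-2 at day 0. Ratios of 2 libraries have exact binomial 95% intervals. The difference between the genotypes' log2 folds has a normal interval on the log scale with 0.5 added to each read count. Both cover counting error only. Total library depth is unknown because only listed genes are in the tables, and the fewest reads of a listed gene at day 4 were 10 in wild type and 12 in lbd16-2. Medians over genes have order-statistic 95% intervals.

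Gene lists were fixed before the data were examined: 270 genes in 16 lists, matched by locus identifier. For a list with at least 3 members carrying values in all 4 libraries, its median was placed among 10000 random lists of the same size, drawn from the genes of the wild-type list and matched in 10 bins of mean expression. This describes these libraries and is no test of the genotypes. The pool holds wild-type-only genes but none of the lbd16-2 list alone, so lists of shared genes lean to the lbd16-2 side. The genes named in the text were LBD16, the 10 genes with the largest log2 fold in each of the wild-type, lbd16-2 and wild-type-only lists among genes at or above the list's median day 4 level, the 5 with the largest difference of log2 folds in each direction among the wild-type-only and the shared genes at or above their own median wild-type day 4 level, all root primordium members, and 2 to 4 members per other list with the largest fold. Groups of up to 5 members were also named, apart from 1 gene that is not reported here. Those outside the rule were chosen after their values were seen. Names and products come from the RefSeq annotation of TAIR10.1, in which 2773 of 2773 listed identifiers matched, 2684 of them protein coding. Its coordinates are not printed because the tables use another release of the build. The 4 genes of the wild-type list alone without lbd16-2 values were left out of genotype differences. Wild-type values of the 594 genes in the lbd16-2 list alone were not analysed here.

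No alternative replaces a replicate. Alternatives were a doubled fold limit, a filter on the day 4 level, the authors' FDR as a threshold, pseudocounts of 0.1 and 5, folds divided by the median fold of the shared genes, reads thinned to 1 depth, levels centred on the shared genes, and random lists drawn without matching or above the median level. Added after the values were seen, 200 draws of Poisson reads for the 2175 genes with values in all libraries, with the same fold in both genotypes, were passed through the same limits as the wild-type-only list. The steps were tested on simulated reads for 2175 genes, 200 of them made 4-fold lower in lbd16-2 at day 4. The counting interval held the true difference for 97.6% of genes, lay above 0 for 53% of the changed genes and excluded 0 for 2.48% of the unchanged ones. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.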

Results

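RNA was measured in leaf explants of Arabidopsis thaliana, from Col-0 wild type and from plants labelled lbd16-2, a mutant of LBD16. LBD16 encodes an auxin-induced LOB-domain transcription factor that acts in lateral root initiation and in callus formation. Explants of the first pair of leaves of 12-day-old plants were taken at day 0 and after 4 days in the dark on callus inducing medium. Such medium contains auxin and cytokinin, and callus formed on it shares regulators with the early lateral root primordium. There was 1 library for each of the 4 groups, so no difference reported here has a replicate check and no p-value was computed. Intervals in parentheses are 95% counting intervals, which cover counting error only and compare libraries, not conditions. The authors' lists hold the genes whose level at day 4 was over 8-fold that at day 0, so genes that fell or changed less were not analysed here. Relative depths, given by the size factors, were 1.43 for wild type at day 0, 1.41 for wild type at day 4, 1.08 for lbd16-2 at day 0 and 1.68 for lbd16-2 at day 4. The 2179 genes of the wild-type list held 94199 reads at day 0 and 2837436 at day 4, and the 2251 genes of the lbd16-2 list held 92884 and 3595214.

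LBD16 itself (AT2G42430) had 20.9 normalised reads at day 0 and 981 at day 4 in wild type, and 34.3 and 518 in the libraries labelled lbd16-2. Its fold was 46.9 (32.7 to 69.8) in wild type and 15.1 (10.9 to 21.6) in lbd16-2, and its day 4 level in lbd16-2 was 0.528 times that in wild type (0.484 to 0.575). LBD16 was therefore in both lists. In the authors' deposited table its FDR was 0.0947 in wild type and 0.579 in lbd16-2. Reads summed over a gene do not show whether the transcript is intact, so they do not check the genotype label, and every direction given for lbd16-2 rests on that label.

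The first comparison asked which genes increased in wild-type leaves over 4 days on the medium. All 22 mitotic genes of the list fixed beforehand were in the wild-type list, as were 18 of 25 root primordium and root stem cell regulators, 12 of 31 Aux/IAA and GH3 auxin response genes and 8 of 11 low-oxygen genes. Lists of these sizes would hold 1.96, 2.23, 2.76 and 0.981 genes if the listed genes were drawn at random from the 24442 tested. None of the 19 DNA replication genes and none of the 10 photosynthesis genes was listed. The list covered 8.91% of the genes tested, with a median log2 fold of 4.56. For 677 of its 2179 genes no read was counted at day 0.

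Among genes at or above the list's median day 4 level, the glycine-rich protein gene AT2G05510 came first by the deposited log2 fold, a rank that depends on its pseudocount, with 0 reads at day 0 and 3205 normalised reads at day 4, at least 1531-fold higher. The defensin-like gene AT3G63360 (2960 normalised reads at day 4), the alternative oxidase gene AOX1B (2403), the cellulose synthase-like gene CSLB02 (2077) and AT4G09940 (1869), which encodes a P-loop nucleoside triphosphate hydrolase, also had 0 reads at day 0. Genes for proteins of the lipid-transfer type reached the highest levels of this group. AT4G15160 went from 34.9 to 70317 normalised reads, 2016-fold (1529 to 2716), and AT5G01870 from 8.37 to 24425, 2917-fold (1670 to 5646). The AT-hook protein gene AHL19 had 1 read at day 0 and 3492 normalised reads at day 4, the DUF642 gene AT2G41800 had 3 reads and 6254, and the LEA-related gene AT5G60530 had 2 reads and 4364. The list was made by fold alone. An FDR under 0.05 was given for 251 of the 2179 genes (11.5%) in the authors' deposited table, where 1097 had a p-value under 0.05 and the largest p-value was 0.339.

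In lbd16-2 the same comparison gave a list of 2251 genes, 9.18% of the 24518 tested, with a median log2 fold of 4.46. The malate transporter gene ALMT1 came first by the deposited log2 fold among genes at or above the median day 4 level, with 0 reads at day 0 and 3344 normalised reads at day 4, at least 1202-fold higher, beside 22.3 and 2220 in wild type. Peroxidase genes were among those with the largest folds. AT4G36430 reached 6726 normalised reads from 2 reads at day 0, AT2G38380 reached 13188 from 7 reads and Prx37 reached 4434 from 2 reads. ERF115, an ethylene response factor that acts in wound-induced regeneration, had 0 reads at day 0 and 2314 normalised reads at day 4, and WOX11, a homeobox gene of root founder cells, had 3 reads and 6037. The polygalacturonase gene ADPG2 (6341 normalised reads at day 4), the PEBP-family gene E12A11 (5437), AT2G41800 (6233) and AHL19 (1433) had 3 reads or fewer at day 0. For 815 of the listed genes no read was counted at day 0. An FDR under 0.05 was given for 202 genes of this list (8.97%) in the authors' deposited table, where 949 had a p-value under 0.05 and the largest p-value was 0.402.

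Most of the increase was common to both genotypes. The lists shared 1657 genes, 76.0% of the wild-type list and 73.6% of the lbd16-2 list, while 522 genes were in the wild-type list alone and 594 in the lbd16-2 list alone. Lists of these sizes drawn independently from 24442 genes would share 201. Over the shared genes the log2 fold in wild type exceeded that in lbd16-2 by a median of 0.22 (0.16 to 0.30, over genes, which are not replicates), with 410 genes above 1 and 294 below -1. This small excess was gone when levels were centred on the shared genes, at -0.045 (-0.102 to 0.035, over genes), with 327 genes above 1 and 357 below -1. The lbd16-2 day 0 library lay 0.47 above the wild-type one on the log2 scale over the 376 shared genes with a mean of at least 20 normalised reads, and centring removes this. The day 4 libraries were offset by 0.04. Counts of shared genes depended on the threshold: at an FDR under 0.05 in the authors' deposited table, 137 genes were shared, 114 were under it in wild type alone and 65 in lbd16-2 alone. Of those 114 genes, 110 were still in the 8-fold lbd16-2 list.

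**Figure D1:**
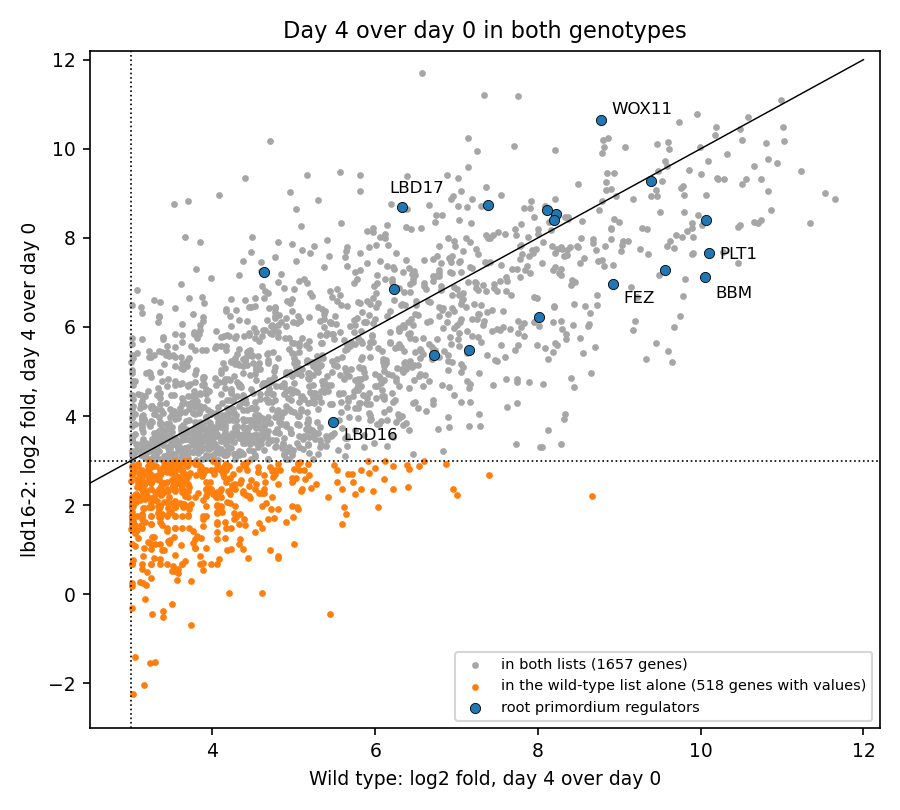
Log2 fold of day 4 over day 0 in wild type (horizontal) and lbd16-2 (vertical), 1 point per gene: grey for the 1657 shared genes, orange for the 518 genes of the wild-type list alone with lbd16-2 values, blue for the 18 root primordium regulators, dotted lines at the list limit of 3 and a solid line of equal folds. Orange points lie under the horizontal limit by construction, and WOX11 and LBD17 lie above the line of equal folds while PLT1, BBM and FEZ lie below it.

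Root primordium and root stem cell regulators were listed as increased in both genotypes, but their day 4 levels moved apart in both directions. All 18 listed members were shared and 0 were in the wild-type list alone, where random lists matched on expression had a median of 3 (percentile 1.76, with ties at their midpoint). That percentile was 9.32 among members above the median day 4 level. The random lists were not matched on wild-type fold, and a gene far above the limit in wild type needs a larger drop to fall under it. The members' median wild-type log2 fold was 8.15, against 3.61 for genes in the wild-type list alone. The low count of wild-type-only members therefore says little about lbd16-2. In each genotype 14 of the 18 had 3 reads or fewer at day 0. At day 4 BBM, PLT1 and PLT2, AP2-type genes of root stem cells, were lower in lbd16-2: BBM had 2542 normalised reads in wild type and 527 in lbd16-2, a ratio of 0.207 (0.193 to 0.223), PLT1 had 1870 and 389 (0.208, 0.191 to 0.227), and PLT2 had 1279 and 439 (0.343, 0.314 to 0.374). FEZ, a NAC gene of root cap stem cells, had 485 and 123 (0.254, 0.216 to 0.297), and AHP6, an inhibitor of cytokinin signalling, had 142 and 43.4 (0.307, 0.231 to 0.403). WOX11 was higher in lbd16-2, with 1049 normalised reads in wild type and 6037 in lbd16-2, a ratio of 5.76 (5.45 to 6.08).

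LBD-family members were among those that differed upward. LBD17 (AT2G42440), the next protein-coding gene to LBD16 in the reference annotation, had 79.2 normalised reads in wild type and 410 in lbd16-2 at day 4 (5.17, 4.23 to 6.37), and LBD33 had 41.0 and 149 (3.62, 2.71 to 4.91). The remaining 10 members differed by less than 1 on the log2 scale. Of these, LBD16, LBD18 (1340 in wild type and 972 in lbd16-2), WOX5 (1071 and 651), PLT3 (9992 and 5988) and SMB (716 and 369) were lower in lbd16-2. LBD29 (495 and 651), WOX7 (275 and 396), PLT7 (596 and 1073), PUCHI (1138 and 1196) and GATA23 (283 and 425) were higher. Counting intervals of the day 4 ratio excluded 1 for 17 of the 18, all but PUCHI. For scale, the middle 50% of 1084 shared genes with a mean of at least 100 normalised reads at day 4 lay between -0.63 and 0.54 on the log2 scale. Of these genes 29.0% differed by over 1 and 8.76% by over 2. The list's median of -0.59 stood at percentile 5.25 of random lists. WOX12, PLT5, SHR, SCR, ARF7, ARF19 and CRF2 were in neither list.

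**Figure D2:**
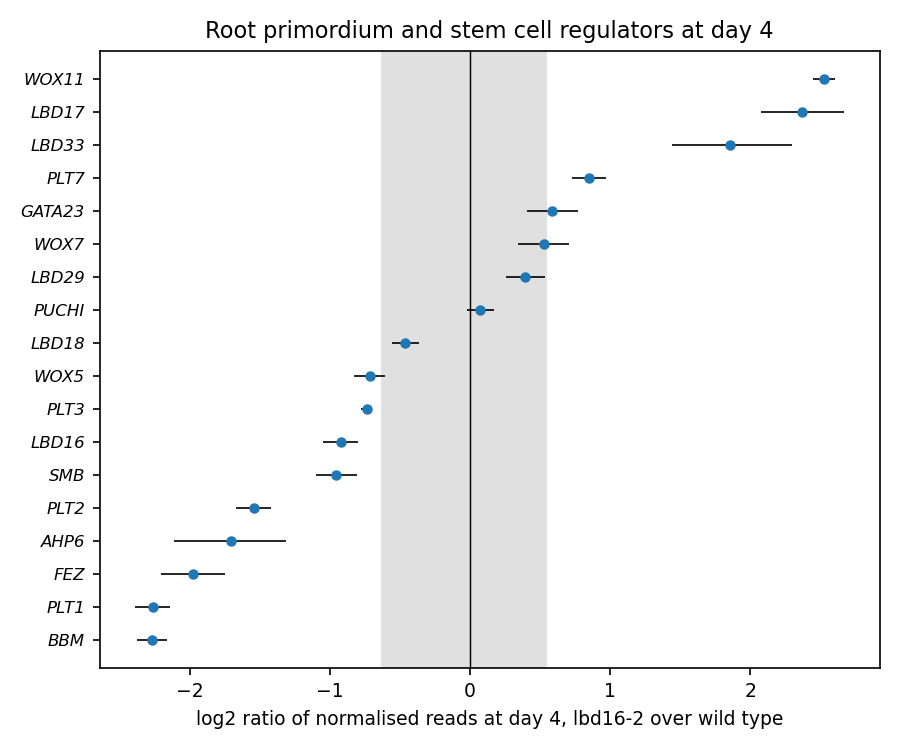
Log2 ratio of normalised reads at day 4, lbd16-2 over wild type, for the 18 listed root primordium and stem cell regulators, 1 library per genotype, with bars for 95% counting intervals and a grey band for the middle 50% of 1084 shared genes, from -0.63 to 0.54. The ratios run from -2.27 for BBM to 2.52 for WOX11, with 3 members above 1 and 5 below -1.

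Mitotic genes were increased in both genotypes. All 22 were in the wild-type list and 19 of them also in the lbd16-2 list, with median log2 folds of 4.03 in wild type and 3.51 in lbd16-2. The B-type cyclin gene CYCB2;1 went from 8.37 to 632 normalised reads in wild type and from 34.3 to 773 in lbd16-2, and CYCB1;1 went from 38.4 to 1259 and from 64.0 to 1115. HIK, a kinesin gene of cytokinesis, reached 3569 normalised reads at day 4 in wild type and 4346 in lbd16-2. CYCA1;1, CDKB2;1 and AUR3 were in the wild-type list alone, with lbd16-2 folds of 7.34, 6.35 and 6.38 that fell short of the 8-fold limit. At day 0 all 22 mitotic genes had a higher level in lbd16-2 than in wild type, with a median ratio of 1.76, and 21 of 22 remained higher relative to the day 0 offset of the shared genes. Their day 4 levels differed by a median of 0.29 on the log2 scale, where the day 4 offset was 0.04. The day 0 median was 0.82, but 0.35 relative to the day 0 offset. The list's median fold difference of 0.52 stood at percentile 69.5 of random lists.

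**Figure D3:**
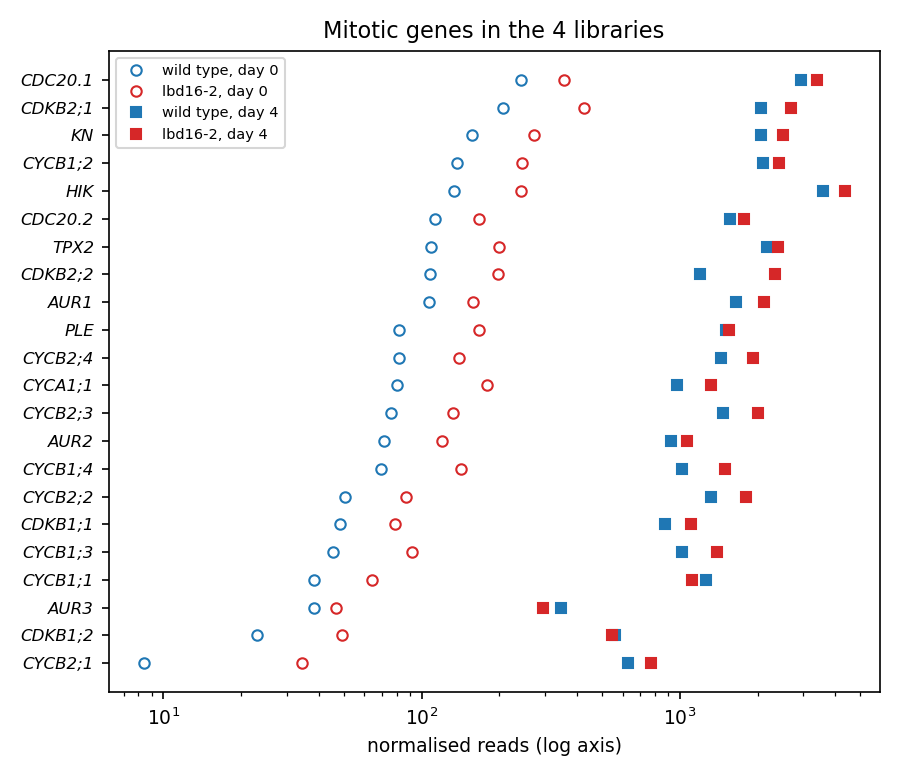
Normalised reads (log axis) of the 22 mitotic genes in the 4 libraries, 1 library per group and so without error bars, open circles for day 0, filled squares for day 4, blue for wild type and red for lbd16-2. Every red circle lies to the right of its blue circle, with a median ratio of 1.76, of which a log2 shift of 0.47 is common to the shared genes at day 0.

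The auxin response genes with the largest folds reached high levels in both genotypes. IAA33 reached only 77.8 normalised reads at day 4 in wild type and 77.9 in lbd16-2. All 12 listed members, 6 of the GH3 family of auxin-conjugating enzymes and 6 Aux/IAA genes, were shared and 0 were in the wild-type list alone (percentile 1.69). Their median wild-type log2 fold was 5.96, far above the limit, so this low count also says little about lbd16-2. GH3.3 went from 59.3 to 42389 normalised reads in wild type, 715-fold (578 to 895), and from 69.6 to 77819 in lbd16-2, 1119-fold (892 to 1422). GH3.2 reached 12805 and 13578 normalised reads at day 4 in wild type and lbd16-2, GH3.1 reached 6131 and 7129, and IAA29 reached 5358 and 6316. Auxin synthesis genes differed more between the genotypes. YUC3, a flavin monooxygenase gene of auxin synthesis, had 260 normalised reads in wild type and 36.3 in lbd16-2 at day 4, a ratio of 0.139 (0.104 to 0.183). YUC9 and YUC8 were in the wild-type list alone, with ratios of 0.178 (0.0924 to 0.321) and 0.229 (0.159 to 0.324). PIN2, an auxin efflux carrier gene of root tips, had 1311 and 309 (0.235, 0.213 to 0.260). The median day 4 difference over these 5 of 20 auxin transport and synthesis genes was -2.08 on the log2 scale, at percentile 0.075 of random lists, and their median fold difference of 2.70 stood at percentile 99.7, which became 97.1, inside the middle 95%, among members above the median day 4 level.

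Other lists divided by tissue and response. Of 13 endodermis and suberin genes 7 were in the wild-type list, 6 of them shared and ASFT in wild type alone, and all 7 had a lower day 4 level in lbd16-2, with a median difference of -0.48 at percentile 39.2. FAR4 had 1071 normalised reads at day 4 in wild type and 960.1 in lbd16-2, CYP86A1 had 510.2 and 326, and GPAT5 had 195 and 111, each enzyme acting in suberin synthesis. Of 11 root hair and epidermis genes 4 were shared, among them RHD6 (328 and 340.1) and WER (ratio 1.11, 0.862 to 1.43), while EXPA7, EXPA18, PRP3 and COBL9 were in the lbd16-2 list alone, at 44.6, 36.3, 32.1 and 52.9 normalised reads. Of 17 shoot meristem and embryo genes 4 were shared. STM, a homeobox gene of the shoot meristem, had 192 normalised reads at day 4 in wild type and 39.2 in lbd16-2 (0.204, 0.153 to 0.268), CUC2 had 188 and 61.2, and RAP2.6L had 1852 and 5716. KNAT1 and KNAT6 were in the wild-type list alone, and CUC1, ESR1 and LEC1 in the lbd16-2 list alone. Of 14 vascular genes WOX4 was listed, in lbd16-2 alone.

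Low-oxygen genes stood toward the lbd16-2 side at day 4, while wound genes went both ways. All 8 listed low-oxygen genes were shared, 7 of them higher in lbd16-2, with a median day 4 difference of 0.54 at percentile 97.5. SUS4 had 1220 normalised reads in wild type and 2000 in lbd16-2, and PDC1 had 2168 and 2732. Of 13 wound and jasmonate genes 4 were shared, 2 higher and 2 lower in lbd16-2, so that their median day 4 difference of 0.86 at percentile 98.5 gives the group no side. ERF114 had 408 and 1725 normalised reads and ERF115 had 669 and 2314, while WIND3 had 6584 and 2656 and JAZ10 had 870.3 and 834. Of 17 cell wall loosening genes 7 were shared, with ADPG2 at 5821 and 6341 normalised reads and XTH20 at 869 and 1956, and XTH18 was in the lbd16-2 list alone. Cytokinin genes numbered 4 of 20, all shared: CKX3, which encodes a cytokinin-degrading enzyme, had 2338 and 3015, and the response regulator gene ARR3 had 292 and 87.4. Of 8 dark and senescence genes NAC092, DIN2 and SAG13 were shared and SAG12 was in the lbd16-2 list alone, with a median fold difference of -1.86 at percentile 0.85. This median of 3 members is the value of DIN2, which had 0 reads at day 0 in both genotypes and a counting interval of -7.12 to 4.21. SAG13 differed by -4.93 and NAC092 the other way, by 0.30. Of 19 ribosome biogenesis genes NUC2 was shared and FIB2 was in the wild-type list alone. Among the 12 lists with at least 3 members carrying 4 values, 2 lay outside the middle 95% of random lists for the fold difference, 3 for the day 4 level and 0 for the day 0 level, where chance gives 0.6 for each. That chance value ignores the pool of the random lists, which holds wild-type-only genes but no genes of the lbd16-2 list alone. Lists of shared genes are thereby placed toward the lbd16-2 side. The 2 for the fold difference were auxin transport and dark and senescence. Above the median day 4 level the first moved inside and the other had too few members for a value, while root primordium regulators at percentile 97.8 and cytokinin genes at 1.14 lay outside.

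The last comparison asked how the genes of the wild-type list alone behaved in lbd16-2. Most of them had a smaller increase, not none: over the 518 with lbd16-2 values the median log2 fold was 3.61 in wild type and 2.27 in lbd16-2, and 311 (60.0%) had an lbd16-2 log2 fold of at least 2. The median difference was 1.62 (1.52 to 1.76). All 518 had a lower fold in lbd16-2, which the lists' limit fixes, and for 388 (74.9%) it was lower by at least 2-fold. Both days held part of the difference. At day 4, 432 of the 518 (83.4%) had a lower level in lbd16-2, by a median of -0.76 on the log2 scale. At day 0, 385 (74.3%) had a higher level, by a median of 0.87, which was 0.46 relative to the day 0 offset. Picking genes by the limit favours both of these directions by itself, and the split it alone would give is not given here. Counting intervals of the fold difference excluded 0 for 267 of the 518 (51.5%), and for 381 of the 1657 shared genes (23.0%). Only 4 of the 522 had an FDR under 0.05 in wild type in the authors' deposited table.

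A raised day 0 level in lbd16-2 marked several of the genes with the largest wild-type log2 fold in this group, among those at or above its median day 4 level. AT5G26260, of the TRAF-like family, had 20.9 normalised reads at day 0 in wild type and 438 in lbd16-2, and 8894 and 2011 at day 4, so its fold was 425 (298 to 630) in wild type and 4.59 (4.17 to 5.07) in lbd16-2. MEE23, of the berberine bridge enzyme family, had 6.28 and 79.8 at day 0, and MC9, a metacaspase gene of xylem cell death, had 15.3 and 184. JAL23, a jacalin-related lectin gene, was named for its difference of log2 folds and had a wild-type log2 fold of only 3.24. It had 25.8 normalised reads in wild type and 327 in lbd16-2 at day 0, and 252 and 112 at day 4. RTFL15 had 0 reads and 13 reads at day 0, and 168 and 82.6 normalised reads at day 4. Others differed mainly at day 4: the chitinase gene AT2G43610 had 5021 normalised reads in wild type and 712 in lbd16-2 (0.142, 0.133 to 0.151), the terpenoid cyclase gene AT1G33750 had 116 and 13.7, and AT5G62420, of the NAD(P)-linked oxidoreductases, had 123 and 18.4. The lbd16-2 fold of AT2G43610 was 7.99 (6.49 to 9.94), only just under the 8-fold limit. AT1G04247, CYP89A6 and PYL3, a gene of the abscisic acid receptor family, were lower in lbd16-2 at day 4. They had 0 reads at day 0 in wild type and 6, 3 and 3 in lbd16-2, with day 4 ratios of lbd16-2 to wild type of 0.511, 0.304 and 0.330. The day 0 counting interval excluded a ratio of 1 for AT1G04247 but not for CYP89A6 and PYL3. The lbd16-2 folds of AT1G04247, CYP89A6 and PYL3 without a pseudocount were 8.44, 9.19 and 9.83, and that of AT1G33750 was 14.7 from 1 read at day 0. The place of these genes in the wild-type list alone therefore depends on the pseudocount of the deposited log2 fold. Within the same limit the smallest differences, in MIF1, EHD2, bZIP44, ENODL14 and NP2, separated wild-type folds of 8.22, 8.30, 8.15, 8.33 and 8.66 from lbd16-2 folds of 7.69, 7.42, 7.26, 7.42 and 7.63, values on either side of the 8-fold limit.

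Among shared genes at or above their median wild-type day 4 level, the largest excess of the wild-type log2 fold was in AT5G59100, a subtilisin-like protease gene with 311 normalised reads at day 4 in wild type and 19.0 in lbd16-2 (0.0612, 0.0414 to 0.0877). It was followed by IQD16 (264 and 45.8), the GILT reductase gene AT4G12870 (441 and 72.5), the pectin lyase-like gene AT1G65570 (279 and 11.9) and the WNK-like gene AT3G15240 (802 and 105). In the opposite direction stood PAD3 and CYP71A13, P450 genes of camalexin synthesis, with ALMT1, SAG13 and the extensin gene EXT4. These had lower day 0 levels in lbd16-2: PAD3 had 60.0 normalised reads at day 0 in wild type and 3.71 in lbd16-2, and EXT4 had 163 and 13.0. CYP71A13, SAG13 and ALMT1 had 24, 20 and 32 reads at day 0 in wild type and 0 in lbd16-2. At day 4 all 5 were higher in lbd16-2, PAD3 at 788 and 2146, CYP71A13 at 299 and 497, SAG13 at 316 and 645, EXT4 at 5900 and 9480, and ALMT1 at 2220 and 3344.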

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

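The tests of the 8-fold limit, of scaling offsets, of primordium cell share, of ordinary variation between samples and of draws with no fold difference were chosen only after the results were seen. Thinning was added after the files were seen, with its limits set before its value was known, as were those of the first counting error tests. The effects in wild type and lbd16-2 had opposite signs for 13 genes of the wild-type list, and with 1 library per group the difference between the genotypes was not tested against replicates. Their log2 folds in lbd16-2 were -2.24 for AT3G56220, -2.04 for TCP1, -1.54 for JAL23, -1.53 for AT5G44440, -1.41 for AT1G31040, -0.69 for KIN1, -0.51 for ESE2, -0.44 for AT1G15330, -0.44 for AT5G41290, -0.38 for AT3G05150, -0.30 for AT4G08125, -0.21 for AT5G26280 and -0.10 for YUC8, while all were above 3 in wild type. The counting interval of the fold difference excluded 0 for all 13, but only JAL23, KIN1, AT5G26280 and YUC8 had at least 10 reads in each library. That interval concerns the difference, which picking by opposite signs makes large, and not the sign in lbd16-2. The lbd16-2 fold was 0.341 (0.284 to 0.409) for JAL23 but 0.928 (0.565 to 1.55) for YUC8. The day 0 offset of 0.47 lowers log2 folds in lbd16-2, so those of smaller size than it have no certain sign. Those of ESE2 and KIN1 were little larger than it, from 16 and 17 reads and from 75 and 72 reads at day 0 and day 4 in lbd16-2. Their sign is not certain either. AT3G56220 and TCP1 rested on at most 6 reads in each lbd16-2 library. KIN1, a cold- and stress-responsive gene, had 43.3 and 590.1 normalised reads at day 0 and day 4 in wild type and 69.6 and 42.8 in lbd16-2.

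The 522 genes in the wild-type list alone invite the reading that their increase needs LBD16. Against counting error as the whole cause, 51.5% of the 518 with values had a fold difference whose counting interval excluded 0, while genes that passed the same limits in 200 draws of reads with no fold difference had a mean share of 4.28% and a highest share of 9.63%. In those draws a mean of 183 genes and at most 212 passed the limits, so counting error could still place part of the list. These numbers are no upper bound. The draws held only genes already in the wild-type list, without genes just under its limit, and left out the day 0 offset. After all libraries were thinned to 1 depth, 87.1% still lay above the limit in wild type and below it in lbd16-2. This cannot decide whether the shallower lbd16-2 day 0 library placed them there. Thinning leaves the reads of that shallowest library nearly as they were, and the genes were picked on those reads. The 8-fold limit itself is a candidate explanation for much of the list, since 60.0% of these genes had an lbd16-2 log2 fold of at least 2, and 118 of 518 (22.8%) passed the limit in lbd16-2 once levels were centred on the shared genes. An effect of the genotype stays open for all of them and was not tested, since each group is 1 library.

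The mitotic genes were higher in the lbd16-2 library at day 0, before the medium could act, by a median of 0.82 on the log2 scale. Counting error alone is argued against by 21 of 22 genes with a counting interval of the ratio above 1. A scaling offset between the day 0 libraries cannot be told apart from a change in these genes: the other 357 shared genes with a mean of at least 20 normalised reads were shifted by 0.44 (0.36 to 0.52), which fell between the limits set for either answer. An earlier form of this test, which required a minimum of reads in each library, favoured the offset and was replaced because such a minimum selects for the shallower library. The lack of a second library of each genotype at day 0 keeps this open.

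Root primordium regulators moved apart at day 4, with WOX11, LBD17 and LBD33 higher in lbd16-2 and BBM, PLT1, PLT2, FEZ and AHP6 lower. A scaling offset is argued against by the range of their log2 ratios, 4.79, since an offset moves all genes alike. A lower share of primordium cells cannot be told apart either: 3 members were higher in lbd16-2 by over 1, but that restates the pattern, and no measure of cell share apart from these genes was used. Ordinary variation between single samples cannot be told apart from the genotype, because each group is 1 library. Of shared genes of like depth, 29.0% also differed by over 1 and 8.76% by over 2. The pattern is therefore not called an effect of the genotype here.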

How the results depend on the processing

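The FDR threshold of 0.05, thinning and centring were alternatives chosen after seeing the data, and the others were planned. Values without replicates were called moved when they left the 95% interval of the median, or when a count changed by over 1.5 times. Of the alternative values for the main results 27 stayed within that range, 23 moved and 1 reversed in sign. The 27 overstate stability. They include the main pseudocount of 1 recomputed from the levels, and the shared genes' day 0 median, which was 0 under each setting. The wild-type and lbd16-2 lists held 1417 and 1363 genes at a doubled fold limit, with 989 shared and 374 in lbd16-2 alone. With the higher day 4 level at or above the median, 1002 were shared, 193 in wild type alone and 192 in lbd16-2 alone. At the authors' FDR under 0.01 these were 64, 74 and 31, and under 0.05 they were 137, 114 and 65, in each case because fewer genes pass. The median fold difference of shared genes was 0.13 with folds divided by the shared median fold. With centred levels, which remove the day 0 offset, it changed sign to -0.045, with an interval that held 0 (-0.102 to 0.035). For wild-type-only genes it was 1.96 and 1.15 with pseudocounts of 0.1 and 5, and 1.40 with centred levels. These and the day 4 and day 0 differences of wild-type-only genes kept their direction under the alternatives run for them. Those were the pseudocounts, the division by the shared median fold, thinning and centring. Picking genes by the limit favours these directions by itself. The day 4 difference of wild-type-only genes was -0.62 with a pseudocount of 5. Their day 0 difference was 0.96 and 0.47 with pseudocounts of 0.1 and 5, 0.95 after thinning and 0.46 with centred levels. The cause was not tested for the pseudocounts and thinning. Lists outside the middle 95% for the wild-type-only count numbered 1 above the median day 4 level, against 2. That count depends on the size of the wild-type fold, on which the random lists were not matched. For single lists 40 percentiles kept their side of that range and 4 moved. The dark and root hair lists had too few members above the median level for a value. Few day 0 reads widen the counting intervals of the folds. No paired analysis was possible because each group has 1 library.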

Other observations

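All groups in this part were chosen after the values were seen. Class III peroxidase genes, whose products act in the cell wall, made up 33 genes of the wild-type list and 39 of the lbd16-2 list, out of 70 in the annotation, where 6.24 and 6.43 would be listed by chance. Cytochrome P450 genes numbered 50 and 51 of 248 (22.1 and 22.8 by chance), WRKY transcription factor genes 20 and 20 of 70 (6.24 and 6.43), SAUR genes of the auxin-responsive growth family 19 and 19 of 78 (6.95 and 7.16), glutathione S-transferase genes 13 and 19 of 56 (4.99 and 5.14), and AT-hook protein genes 7 and 6 of 20 (1.78 and 1.84). Genes annotated as mannose-binding lectins of the jacalin type numbered 9 and 11 of 34 (3.03 and 3.12). Families were taken by product name, so JAL23, annotated as a jacalin-related lectin, is not counted there. Members of such families can share reads, so single members are less certain than the totals.

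Some defence genes differed between the genotypes at day 0. Of 19 genes of camalexin synthesis, salicylate and pathogen response, 6 were shared and 5 were in the lbd16-2 list alone. The shared ones were PAD3, CYP71A12, CYP71A13, FMO1, SAG13 and FRK1. Their median difference between lbd16-2 and wild type was -2.48 at day 0 and 0.88 at day 4 on the log2 scale, and their median fold difference was -3.50, in a group picked for these values, so that its place among random lists has no weight. At day 0 PAD3, CYP71A13 and SAG13 were lower in lbd16-2, CYP71A12 had 14 reads in each genotype, and FMO1 and FRK1 had 2 reads in wild type and 0 in lbd16-2. PR1, BGL2, GSTF6, GSTF7 and UGT76B1 were in the lbd16-2 list alone, at 24.4, 903, 5440, 4081 and 592 normalised reads at day 4. Whether they were lower in wild type at day 4 or higher at day 0 was not analysed here.

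LBD17 adjoins LBD16 in the annotation and was 5.17 times as high in lbd16-2 at day 4. Among the 20 nearest protein-coding genes 1 other, AT2G42460, was listed, with 11 reads in wild type and 16 in lbd16-2 at day 4.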
